A study of Homo sapiens with 4 samples.

How the data were processed

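Total RNA from MHCC-LM3, an established human hepatocellular carcinoma cell line, was profiled on 4 Affymetrix whole-transcript expression arrays, 1 per sample. The labels describe cells given 50 µM zerumbone, a sesquiterpene from ginger plants, or the solvent DMSO, for 24 h, with 2 arrays in each group. The group of each array was taken from its source label. The arrays of a group carry no replicate number in the labels and were numbered in the order of deposit, so no array of one group is paired with an array of the other. The labels give no batch. The array titles run in sequence through the DMSO arrays and then the zerumbone arrays, so an order or batch of processing that followed the titles would coincide with the groups.

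The authors deposited 1 table of log2 expression values for all arrays. Per the submitters' processing notes, the values were made with RMA in the Affymetrix Expression Console, without a version of either. RMA subtracts a background, makes the distributions of the arrays equal and summarises the probes of a transcript cluster on the log2 scale. The design text calls the array a human exon array, whereas the row names and the probe annotation belong to a transcriptome array of the same maker, and the annotation was used as given. The deposited log2 values reach 19.93 on both DMSO arrays, above the 16 bits of a scanner. A further step after RMA therefore cannot be excluded, and every difference and fold is on the scale of the deposited values. Array medians over the transcript clusters were 3.86 and 3.83 under DMSO and 3.96 and 3.92 under zerumbone. No genome build is given in the sources used here, and no coordinates are reported.

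The table has 70523 rows. Of these, 2995 control and probe-region rows were left out of the tests, which leaves 67528 transcript clusters. Through the probe annotation, 23781 clusters carry 1 gene symbol, 1543 carry several and 42204 carry none. Clusters with 1 symbol were reduced to 22465 genes by keeping, for the 479 genes with more than 1 row, the row with the highest mean over the 4 arrays. For 30 called genes, the rows of the gene differ in sign. Some symbols of the gene lists were updated to current names by hand. Some genes chosen in advance have no row of their own and are not analysed here.

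Differences are zerumbone minus DMSO on the log2 scale. They were tested with lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 22465 genes and a threshold of 0.05 on the adjusted p. Residual degrees of freedom were 2 and the prior added 2.88. "Rose" and "fell" are used for genes past that threshold. A gene was taken to be at background level in a group when it lay, on both arrays of the group, under the 95th percentile of 23 antigenomic background rows. A fold against such a group is given as a lower bound, with that percentile in place of a dimmer value. For a gene under the percentile on only 1 array of a group, no size of change is given. Counts of list members that rose or fell include called genes at background level in both groups. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

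A total of 40 gene lists with 906 members was fixed before the data were examined, and 795 members were measured. The lists cover glucose, energy, lipid and nucleotide metabolism, stress responses, cell cycle, signalling, and markers of hepatocytes and of other cell types. Each list was tested with camera from limma at its preset correlation of 0.01, with adjustment over the 40 lists. The same lists were tested with the correlation estimated from the arrays and with fry. Each list's calls were also counted with p-values adjusted over the list alone. With 2 residual degrees of freedom the correlation between genes is poorly estimated. In that setting camera also takes its p-values from these 2 degrees of freedom, so they are large even where the estimated correlation is low.

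The rule for named genes was also fixed beforehand. It takes the 12 largest rises and 12 largest falls among called genes whose zerumbone values both lie beyond both DMSO values, leaving out microRNA, small RNA, LOC, LINC and open-reading-frame names. It further takes up to 4 called members of each list with the largest change, and a fixed set of glucose metabolism and reference genes whatever their result. Genes that go against a list's direction, HK1, GAPDH, H6PD, the microRNA genes and the genes of the proteasome and YAP tests (THBS1 and CCN1 included) fall outside this rule and were named after their values were seen.

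The steps were tested on simulated data built from the means and spreads of these 22465 genes. With 50 genes changed at each size, 200 in all, the test recovered 0% of changes of 0.25, 66% at 0.5, 96% at 1 and 100% at 2 on the log2 scale. The adjusted threshold is stricter when few genes change, so these rates do not carry over to the arrays, where 2637 called genes changed by less than 0.5. Recovery was not counted in the simulation with more changed genes. The share of false calls averaged 9.34% over 20 draws with 200 changed genes, above the nominal level. It was 3.65% in a simulation with 7488 changed genes. In a further simulation genes varied independently and only the glycolysis list was shifted, by -0.5. Camera recovered the shift at its preset correlation, with 0 other lists called, but not with an estimated correlation (adjusted p 0.144). With no correlation between genes built in, that simulation cannot tell which setting is right for these arrays.

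The alternatives fixed beforehand were a variance trend with and without robust estimation, median centring, cyclic loess, a filter on dim genes and the mean of a gene's rows. An adjusted threshold of 0.01, a minimum fold of 1.5 with treat in limma, all transcript clusters and leaving out each array in turn were also fixed beforehand. Leaving out genes at background level or at the upper end of the scale in both groups was added after the data were seen. The upper end is within 0.5 of an array's maximum.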

Results

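Gene expression was measured in MHCC-LM3 hepatocellular carcinoma cells after 24 h with 50 µM zerumbone or with DMSO, with 2 arrays in each of the 2 groups. The title of the series names glucose metabolism as the subject. The comparison asks which transcripts differ after the compound, and whether those of glucose metabolism are among them. The number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

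ZFAND2A, a stress-induced partner of the proteasome, averaged 9.21 ± 0.124 (SD, n = 2) log2 units under DMSO and 14.45 ± 0.056 (SD, n = 2) under zerumbone, a 37.9-fold rise. GABARAPL1, an autophagosome membrane protein, rose 37.8-fold. CYP24A1, the enzyme that inactivates vitamin D, went from 12.59 ± 0.102 (SD, n = 2) to 6.13 ± 0.221 (SD, n = 2), an 87.9-fold fall. AKR1B10, an aldo-keto reductase, went from 18.46 to 12.36 and TGFB2, a growth factor ligand, from 11.67 to 5.64.

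Other large rises were in UPP1 (5.04), a uridine phosphorylase, PPP1R15A (5.04), a subunit of the phosphatase that acts on eIF2 alpha, and CTH (4.89), which makes cysteine. MT2A, a metal-binding protein, rose by 4.81, SESN2, a stress-induced regulator of growth signalling, by 4.64 and MAP1LC3B, an autophagosome marker, by 4.39. The chaperone genes HSPA6 and HSPA7 rose by 4.62 and 4.98, but they are near-identical in sequence and their probes may not tell them apart. BAG3 and HSPB8, which act together in chaperone-assisted autophagy, rose by 4.59 and 4.41.

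Other large falls were in H1-4 (-5.07), a linker histone, LMNB1 (-5.01), a nuclear lamina protein, TYMS (-4.85), which makes thymidylate, and SOX4 (-4.60), a transcription factor. CCNA2 (-4.58), an S and G2 phase cyclin, and MKI67 (-4.54), a marker of dividing cells, fell as well. FAM111B, RARB and CDH6 were at background level under zerumbone, and fell at least 15.5-fold, 15.1-fold and 16.1-fold. These 24 genes had adjusted p-values in limma from 3.50e-05 to 1.22e-04.

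In total, 8091 of 22465 genes (36.0%) passed the limma threshold, 4125 higher and 3966 lower under zerumbone. Rises of at least 1 on the log2 scale were counted for 1118 genes and falls of that size for 1424, and for changes of at least 2 the counts were 201 and 374. The median absolute change of a called gene was 0.69, and 2637 called genes changed by less than 0.5. Without DMSO replicate 1 the number higher was 2557, and without DMSO replicate 2 it was 2687. The share of called genes that were higher was 51.0%, against 41.0% after centring each array on its median and 46.2% after cyclic loess.

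**Figure D1:**
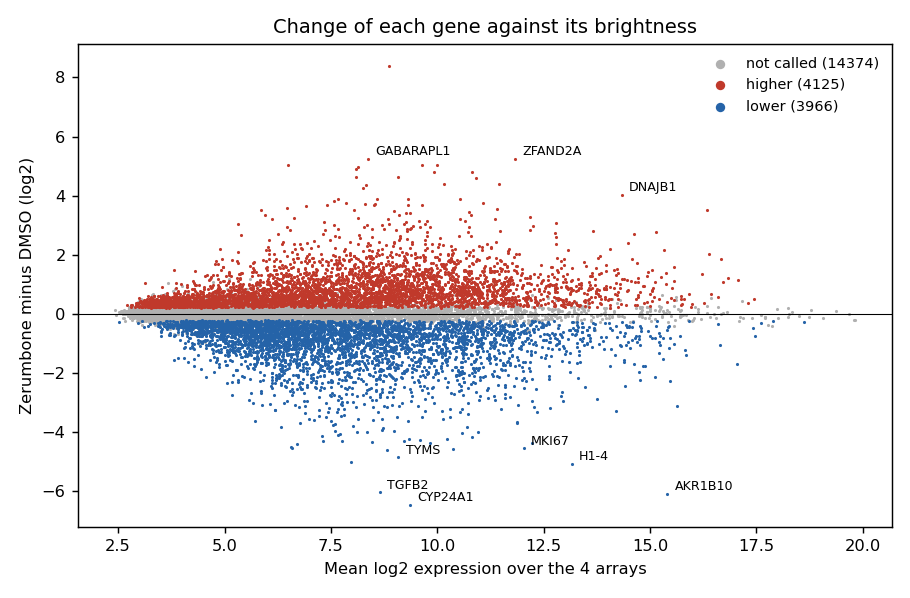
Zerumbone minus DMSO difference of each gene on the log2 scale (vertical axis) against its mean log2 expression over the 4 arrays (horizontal axis). Each point is 1 of 22465 genes. The 4125 called higher and 3966 called lower are coloured, and AKR1B10 and CYP24A1 lie lowest at -6.09 and -6.46.

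The arrays of a group resembled each other more than those of different groups. Across genes, which are not independent replicates, Pearson's r was 0.998 between the DMSO arrays, 0.997 between the zerumbone arrays and 0.931 to 0.933 between groups. The first principal component, which separated the groups, held 94.4% of the variance. Of 10978 genes at background level in both groups, 771 were called, 600 of them higher, and the 23 background rows were themselves higher by a median of 0.0785 on the log2 scale.

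Genes of glycolysis, the breakdown of glucose to pyruvate and lactate, were lower under zerumbone. Of 23 measured members 16 fell, 0 rose and 7 did not pass, with the same counts when adjusted over the list alone. LDHA, which reduces pyruvate to lactate, went from 12.45 ± 0.020 (SD, n = 2) to 11.04 ± 0.042 (SD, n = 2), a 2.66-fold fall. PGAM1 (-1.31), LDHB (-1.17) and GPI (-1.06) had the next largest falls. All 3 phosphofructokinase genes fell, PFKM by 1.04, PFKP by 0.99 and PFKL by 0.63, as did SLC2A1, a glucose transporter, by 0.85, PKM by 0.64 and PFKFB3 by 0.58.

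HK2, a hexokinase often abundant in liver cancer, was at background level in both groups, at 3.38 under DMSO and 3.42 under zerumbone, with a limma adjusted p of 0.669. The 16 falls included the other hexokinase measured, HK1 (-0.32), whose call was lost whichever array was left out (adjusted p from 0.0521 to 0.141). GAPDH differed by -0.13 without passing. The median difference of the list was -0.55, with a camera adjusted p of 1.08e-06 and an adjusted p of 0.210 with an estimated correlation. TIGAR, which lowers glycolytic flux, differed by 0.19 with a limma adjusted p of 0.235.

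In the pentose phosphate pathway, which makes NADPH and ribose from glucose, 6 of 10 measured members fell, 3 rose and 1 did not pass. Adjusted over the list alone, 6 were lower and 4 higher. PRPS2 (-1.94) and RPIA (-1.69) fell, as did TKT, a transketolase, from 13.74 to 12.14, a 3.04-fold change. TALDO1 fell by 1.14, H6PD by 1.04 and PGD by 0.81, whereas PRPS1 and PGLS rose by 0.42 and 0.34 and RBKS, a ribokinase under background level on 1 DMSO array, rose as well. PRPS1 lost its call without DMSO replicate 1 (adjusted p 0.0573), and PGLS without DMSO replicate 1 (0.178), DMSO replicate 2 (0.122) or zerumbone replicate 2 (0.0842) and after median centring (0.118) or cyclic loess (0.0534). The list as a whole was not called by camera, with an adjusted p of 0.0768 against 0.00386 with fry, which does not compare the list with other genes. The median of the list was -0.93.

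**Figure D2:**
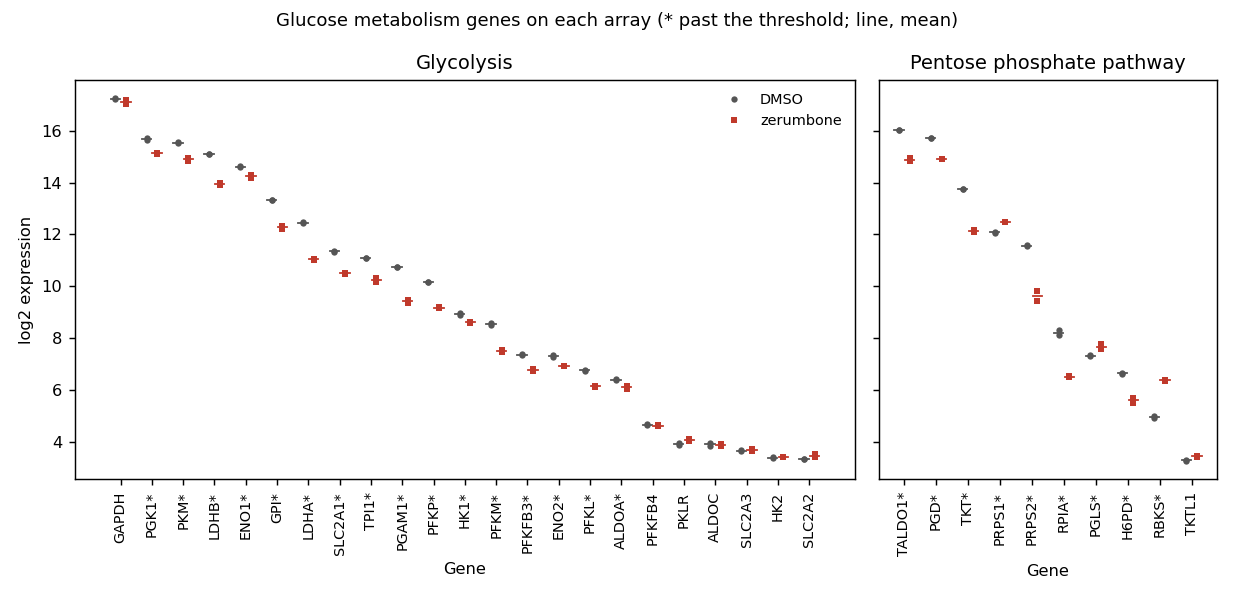
log2 expression of the 23 glycolysis genes and 10 pentose phosphate pathway genes on each array (vertical axis), ordered by their DMSO mean. Circles are DMSO arrays, squares zerumbone arrays, short lines group means and an asterisk a gene past the limma threshold. HK2 sits near 3.38 in both groups, while LDHA and TKT lie lower on both zerumbone arrays.

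Downstream energy metabolism was also lower for many genes. Of 44 oxidative phosphorylation genes 26 fell and 4 rose (28 and 5 adjusted over the list alone), led by CYC1 (-1.84) and ATP5F1D (-1.47). The rises were in NDUFA5, NDUFB5, NDUFA6 and COXFA4, with the call of NDUFB5 lost without DMSO replicate 1 (adjusted p 0.0648) and that of COXFA4 without DMSO replicate 2 (0.0650). Camera gave this list an adjusted p of 1.20e-05, against an adjusted p of 0.210 with an estimated correlation. Of 25 genes of the TCA cycle and pyruvate entry 12 fell and 2 rose (13 and 3 adjusted over the list alone), among them SUCLG2 (-1.98) and IDH2 (-1.62), with DLST and ME2 as the rises. By camera, the adjusted p was 0.00605, against an adjusted p of 0.224 with an estimated correlation, and the call was lost at 0.0759 with dim genes left out. In fatty acid synthesis and storage 11 of 19 genes fell and 3 rose (11 and 4 adjusted over the list alone). FASN, the fatty acid synthase (-4.32), ELOVL6 (-2.56), SCD (-2.25) and ACACA (-1.89) fell, while PLIN2, a lipid droplet protein, LPIN1 and ACSS2 rose by 1.60, 0.81 and 0.45. The camera adjusted p was 0.00208, against an adjusted p of 0.210 with an estimated correlation.

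Cell division genes fell almost as a block. Of 33 measured G2/M and mitosis genes 32 fell and CDC25C did not pass, and the counts were the same when adjusted over the list alone. PLK1, a mitotic kinase, fell by 4.37 and KIF20A, a mitotic kinesin, by 3.31. The median was -2.30, with a camera adjusted p of 1.11e-23 and an adjusted p of 0.210 with an estimated correlation. Of 32 DNA replication and G1/S genes 30 fell and 1, CCNE1 (0.93), rose (30 and 2 adjusted over the list alone). MCM10 fell by 4.11, PCNA, the replication clamp, by 3.56, GINS1 by 3.31 and MCM4 by 3.10. Camera gave this list an adjusted p of 2.57e-18, against an adjusted p of 0.184 with an estimated correlation.

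All 8 measured replication-dependent histone genes fell, with the same count adjusted over the list alone, H4C3 by 3.65. H2BC3, at background level under zerumbone, fell at least 1.39-fold. Histone genes are close in sequence, so probes may be shared. By camera, the adjusted p was 1.20e-05, against an adjusted p of 0.203 with an estimated correlation. In purine and pyrimidine synthesis 15 of 18 genes fell and 0 rose (17 lower adjusted over the list alone), among them PAICS (-3.12), RRM2 (-2.49) and CAD (-2.06). The camera adjusted p was 1.09e-11, against an adjusted p of 0.184 with an estimated correlation.

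Of 22 ribosome biogenesis genes 20 fell and 1 rose (21 and 1 adjusted over the list alone), UTP20 by 2.38 and MYBBP1A by 2.15, while RRP12 rose by 1.13. Camera gave this list an adjusted p of 2.62e-12, against an adjusted p of 0.203 with an estimated correlation. Ribosomal protein genes moved little. Of 25, 8 fell and 0 rose, with the same counts adjusted over the list alone, and the median was -0.18. By camera, the adjusted p was 4.03e-04, against an adjusted p of 0.348 with an estimated correlation. Of 11 tubulin genes 5 fell and 1 rose, with the same counts adjusted over the list alone, including TUBB (-2.22) and TUBG1 (-1.79), while TUBB2A rose by 1.01. The camera adjusted p was 0.0292, against an adjusted p of 0.338 with an estimated correlation. Without DMSO replicate 1 it was 0.0645 and without DMSO replicate 2 it was 0.0552, so either loss ended the call.

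Of 25 integrated stress response genes, targets of the transcription factor ATF4 and ATF4 itself, 21 rose and 1, the amino acid transporter SLC7A5 (-1.04), fell (22 and 1 adjusted over the list alone). PPP1R15A, CTH and SESN2, named above, are members. The median was 1.93, with a camera adjusted p of 4.59e-10 and an adjusted p of 0.184 with an estimated correlation. Of 17 heat shock response genes 14 rose and 0 fell (16 higher adjusted over the list alone), with DNAJB1 at 4.04 and HSPA1A at 3.52. HSPA1L, at background level under DMSO, rose at least 7.43-fold. HSPA1A and HSPA1L are close paralogs whose probes may be shared. Camera gave this list an adjusted p of 1.09e-08, against an adjusted p of 0.184 with an estimated correlation.

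Of 27 proteasome subunit genes 25 rose and 0 fell, with the same counts adjusted over the list alone. PSMD12 (1.66), PSMD2 (1.60), PSMD6 (1.53) and PSMC4 (1.52), all of the regulatory particle, rose most. By camera, the adjusted p was 3.03e-10, against an adjusted p of 0.184 with an estimated correlation. Of 22 autophagy and lysosome genes 18 rose and 0 fell, with the same counts adjusted over the list alone. The lysosomal channel MCOLN1 rose by 2.33 and ATG12 by 1.92. The camera adjusted p was 6.77e-07, against an adjusted p of 0.203 with an estimated correlation.

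Of 9 genes in the metallothionein list 6 rose and 0 fell (7 higher adjusted over the list alone), MT2A by 4.81. Of the 6, 2 were at background level in both groups, and MT1X was under it on 1 DMSO array. MT1G was at background level under DMSO, and its size of change is not measured. Metallothionein genes are near-identical in sequence, so members may share probes. Camera gave this list an adjusted p of 6.82e-04, against an adjusted p of 0.269 with an estimated correlation. Of 19 p53 target genes 12 rose and 4 fell (13 and 4 adjusted over the list alone). GADD45A rose by 3.35, TNFRSF10B, a death receptor, by 2.51, PMAIP1 by 1.76 and CDKN1A, a cyclin-dependent kinase inhibitor, by 1.54. DDB2, BAX and XPC fell by 0.42 or less, and TP53I3, at background level under zerumbone, fell too. Without either DMSO array all 4 lost the call (adjusted p from 0.0791 to 0.192), TP53I3 also without either zerumbone array (0.0723 and 0.0927) and BAX without zerumbone replicate 2 (0.0649). By camera, the adjusted p was 0.0134, against an adjusted p of 0.338 with an estimated correlation. Of 19 hypoxia genes outside glycolysis 11 rose and 1 fell, with the same counts adjusted over the list alone. They included DDIT4 (3.88), also a member of the integrated stress response list, NDRG1 (2.93), the mitophagy receptor BNIP3L (2.42) and P4HA2 (2.35), a collagen prolyl hydroxylase. HILPDA fell by 0.78. The camera adjusted p was 0.00122, against an adjusted p of 0.210 with an estimated correlation.

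Genes of the NRF2 and glutathione list, which serve detoxification, went mainly down although HMOX1, a haem oxygenase in that list, rose from 9.21 ± 0.291 (SD, n = 2) to 12.95 ± 0.005 (SD, n = 2). Of 28 members 17 fell and 4 rose, with the same counts adjusted over the list alone. GPX2 fell by 3.59 and AKR1C3 by 2.82, and the AKR1C genes are close paralogs whose probes may be shared. Besides HMOX1, SQSTM1 (0.80), OSGIN1 (0.59) and PIR (0.52) rose. The median was -0.52, with a camera adjusted p of 1.32e-05 and an adjusted p of 0.240 with an estimated correlation.

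**Figure D3:**
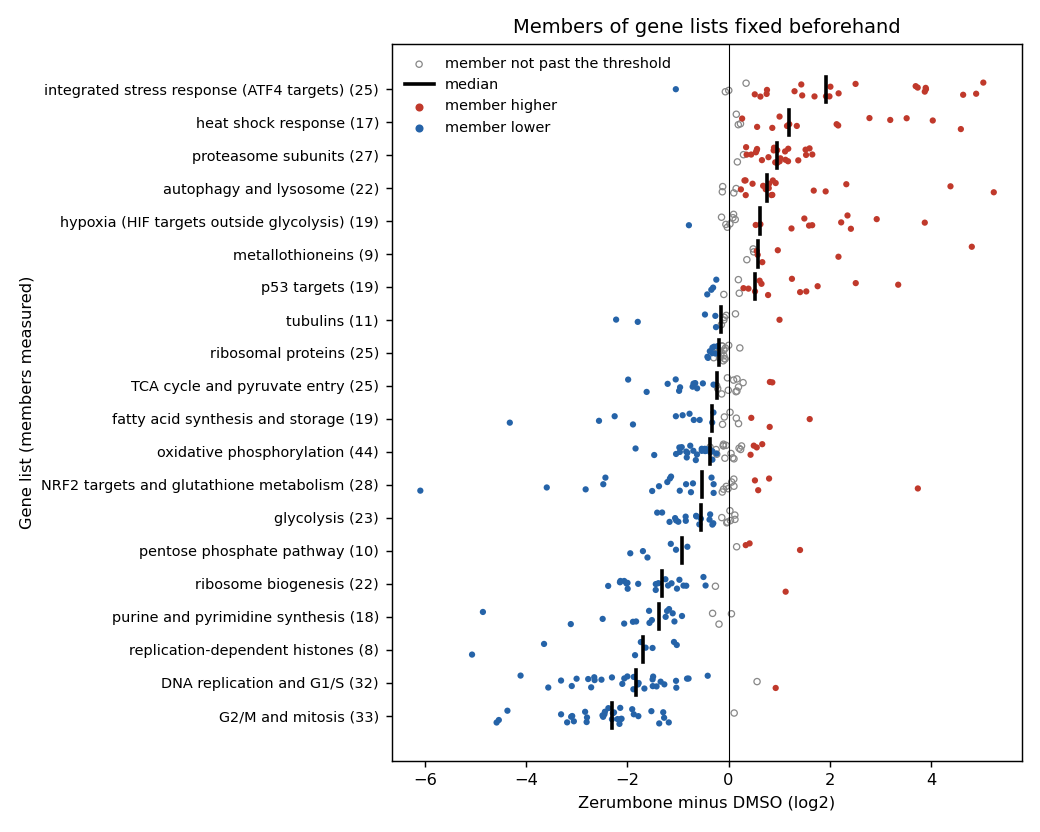
Zerumbone minus DMSO difference on the log2 scale (horizontal axis) of each measured member of the 19 called gene lists and of the pentose phosphate pathway (vertical axis, with the number of members). Filled points passed the limma threshold, open points did not, and black bars are medians, which run from -2.30 for G2/M and mitosis to 1.93 for the integrated stress response.

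Camera called 19 of the 40 lists, 7 higher and 12 lower. None of these 19 calls held with an estimated correlation, where the smallest adjusted p was 0.184 and 8 lists had an unadjusted p under 0.05. A high correlation is not the reason in every list. For DNA replication and G1/S the estimate was -0.022, under the preset 0.01, yet the camera p went from 1.29e-19 to 0.00916. For G2/M and mitosis the estimate was higher, at 0.289. Fry called 35 lists. The other 21 lists had camera adjusted p-values from 0.0768 to 0.944, and for 8 of them the median, the mean and the direction of the test differed in sign.

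Among lists not called, 10 of 19 cholesterol synthesis genes rose and 3 fell, with HMGCS1 at 2.62 and DHCR7 at -1.33, and the camera adjusted p was 0.0946. After median centring that list passed at 0.0328 and after cyclic loess at 0.0271. Of 23 immediate early and MAPK feedback genes 13 rose and 6 fell, with DUSP1 at 4.36 and KLF6 at 3.54, and the adjusted p was 0.112. After median centring this list passed at 0.0197 and after cyclic loess at 0.0271. In the unfolded protein response of the endoplasmic reticulum 8 of 20 genes rose and 5 fell, with HERPUD1 at 2.56 and HSPA5 at 1.86, and the adjusted p was 0.394. For STAT3 targets 6 rose and 6 fell of 24, with an adjusted p of 0.944, and STAT3 itself differed by -0.02 with a limma adjusted p of 0.892. Of 22 apoptosis regulators 6 rose and 6 fell, with MCL1 at 1.28 and BCL2L1 at -0.69, and the adjusted p was 0.546.

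Markers of hepatocytes were mostly not above background. Of 25 measured, 19 were at background level in both groups, 5 fell and 1 rose, and the camera adjusted p was 0.394. The rise, CYP3A4, and 1 of the falls, FGA, were among the 19. ALB, the serum albumin gene, was at 4.56 under DMSO and 4.84 under zerumbone with a limma adjusted p of 0.105. AFP, the alpha-fetoprotein gene, was at 4.04 and 4.25 with an adjusted p of 0.274. Of markers of cell types a culture of this line should not hold, 11 of 14 leukocyte, 10 of 12 endothelial, 8 of 11 fibroblast and 4 of 4 erythroid genes were at background level in both groups, and camera called none of these lists. Fry called the leukocyte list higher (adjusted p 0.00220) and the endothelial (0.00326) and fibroblast (0.00107) lists lower.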

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

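The tests of the background rows, of the hybridization controls and of the genes with small RNA, LOC, LINC or open-reading-frame names were chosen after the results they bear on were seen. The test of those names against background replaced an unmatched version that had been written before the results and pointed the same way.

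Several signals lie in rows that the comparison of genes does not use. The antigenomic background rows had a median zerumbone minus DMSO difference of 0.0785. The 4 hybridization controls, bacterial transcripts spiked in before hybridization, were higher by a median of 0.528, all 4 on both zerumbone arrays. The 4 poly-A controls differed by a median of 0.518, but only 2 were higher on both zerumbone arrays than on both DMSO arrays. Of the others, thr went the other way at -0.57. The 92 rows of the ERCC spike-in set differed by a median of 0.261, with 49 of them higher on both zerumbone arrays than on both DMSO arrays. The ERCC medians were 3.33 and 3.37 on the DMSO arrays and 3.54 and 3.85 on the zerumbone arrays. These lay under the background level, which ran from 4.54 to 5.10 over the arrays. Among transcript clusters without a symbol, 2382 were called higher and 1983 lower, and among those with several symbols 252 were higher and 197 lower, by limma over all clusters.

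Dim genes leaned upward in the zerumbone arrays. Over 10978 genes at background level the median difference was 0.0796, and 76.1% were higher. Array background that the normalization left in place was a candidate, as the antigenomic rows shifted by a median of 0.0785. By array, their medians were 3.10 and 3.12 under DMSO and 3.12 and 3.20 on zerumbone replicates 1 and 2. That shift lay mainly on zerumbone replicate 2, the array with the brighter hybridization controls. At the dim genes, however, replicate 2 differed from replicate 1 by only -0.0154. The dim genes therefore did not follow the antigenomic rows between these 2 arrays. Neither array background nor brighter hybridization of the zerumbone arrays was settled as the cause.

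The NRF2 list was lower while HMOX1 rose. The tables argue against compression of bright signals on the zerumbone arrays, because the list median of -0.52 lies at the 0.06th percentile of 10000 brightness-matched random lists, whose central range was -0.26 to 0.38. Probes shared between the AKR paralogs are not the whole reason either, since 13 of the 24 other members fell by limma, with a median of -0.30 and a camera p of 6.82e-04 (adjusted p 0.316 with an estimated correlation). Why HMOX1 rose was not tested. An order of array processing that followed the groups stays open.

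Genes with small RNA, LOC, LINC or open-reading-frame names were called higher 485 times and lower 118 times. The kinds of name differed. Leaving out genes at background level in both groups, RNU and RNA5 names were called higher 149 times and lower 10 times, and SNOR names 41 and 11. MIR names had 46 and 29, open-reading-frame names 25 and 16, LINC names 23 and 16, and LOC names were near even at 12 and 11. Among those with a mean over the 4 arrays above background level, 261 of 334 (78.1%) were higher, against 40.4% to 50.9% in 95% of 10000 draws of other called genes matched on brightness. The comparison cannot decide on a shift that depends on brightness alone. Unchanged genes would be called mostly higher under an upward shift, whereas the matched genes may be called for falls of their own. Genes are also not independent. Outside the U and 5S RNA names (RNU and RNA5) the share was 66.7% (126 of 189), against 38.1% to 52.4% in matched draws, so near-identical copies of these genes are not the whole cause. Fragmented or differently labelled short RNA was not tested, and a change in the cells stays a hypothesis.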

How the results depend on the processing

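One alternative, leaving out genes at the ends of the scale, was chosen after the data were seen. Among 210 named genes, 40 lists and the 3 gene sets of the proteasome and YAP tests, none was called in one direction and had the other under an alternative. Over all 8091 called genes, 5 had the opposite sign with the mean of all rows. The number of called genes was 2845 with a minimum fold of 1.5 (1253 higher, 1592 lower), and 2715 were higher at an adjusted p under 0.01, as both are stricter criteria. Leaving out 1 array each, the counts ran from 5458 to 7464 for all, 2557 to 3822 for higher and 2854 to 3642 for lower genes. In those fits the glycolysis adjusted p ran from 1.47e-06 to 6.59e-06, that of the pentose phosphate pathway from 0.0601 to 0.0858, and the lists called from 18 to 19. The lone array is then assumed to vary like the other group. With an estimated correlation the glycolysis adjusted p was 0.210 and 0 of 40 lists were called, with 8 at an unadjusted p under 0.05. In simulated data with independent genes, a shift of the glycolysis list alone was also missed with an estimated correlation (adjusted p 0.144). The setting can therefore miss a shift, but this does not tell whether a call lost here was a true one. With fry, which does not compare a list with other genes, the pentose phosphate pathway passed at 0.00386 and 35 lists were called. Among 1461 values of named genes under the other alternatives 4 lost their call, and among 840 with 1 array left out 46 did. The genes concerned were LYVE1, PECAM1, DCN, RPL35, RPS25, RPL7, RPS23, TUBA1B, CEBPA, FGA, PGLS, BAX, DDB2, XPC, NDUFB5, COXFA4, PRPS1, HK1 and TP53I3. Whichever array was left out, DCN, HK1, PECAM1 and TP53I3 lost it. The immunoproteasome set had a p of 0.0783 with an estimated correlation, and the proteasome genes outside the fixed list were lower at 0.0295 with fry. For gene lists under the other alternatives 5 of 277 values lost a call and 5 gained one. The tubulin list was lost after cyclic loess (0.121), with dim genes left out (0.130) and with genes at the ends of the scale left out (0.214), and the TCA list with dim genes (0.0759) and genes at the ends left out (0.118). Fetal liver markers passed with genes at the ends of the scale left out (0.0369). Median centring kept 7141 of the 8091 called genes in the same direction and cyclic loess 7519. No paired analysis was possible because the labels give the groups no shared replicate numbers. With 10978 genes at background level in both groups, no fold is given for such genes.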

Other observations

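The tests of the proteasome and YAP hypotheses were written before their results were seen, whereas the microRNA genes below were chosen after their values were seen.

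Of 23 interferon-stimulated genes 4 fell, 1 rose and 13 were at background level in both groups (camera adjusted p 0.278). OAS3 (-3.54) and OAS1 (-3.13), sensors of double-stranded RNA, fell, as did OAS2, under background level on 1 zerumbone array, and ISG20 rose by 0.89. Of 21 NF-kB targets 7 fell and 4 rose, and the camera adjusted p was 0.109. TNFAIP2 fell by 2.05 and CCL20, at background under zerumbone, at least 2.55-fold. In the PI3K, AKT and mTOR list, 8 of 24 genes rose and 9 fell (camera adjusted p 0.313). IRS1, an adaptor of the insulin receptor, fell by 2.76, while its relative IRS2, at background under DMSO, rose at least 2.92-fold. Fry called these 3 lists lower, with adjusted p-values of 0.00386, 0.00708 and 0.0431. CCND1, a G1 cyclin in the STAT3 target list, fell by 4.26.

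In xenobiotic metabolism 5 of 17 genes fell and 4 rose (camera adjusted p 0.355). CYP1B1 fell by 3.94, UGT2B7 by 3.41 and the drug pump ABCG2 by 3.23, whereas the drug pump ABCB1 rose by 2.80. In the one-carbon list, 4 of 11 genes fell and 3 rose (camera adjusted p 0.624), with MTHFD1 at -3.31 and PSAT1 at 1.88. In gluconeogenesis and glycogen 6 of 15 fell and 2 rose (camera adjusted p 0.133), and in fatty acid oxidation 9 of 22 fell and 7 rose (camera adjusted p 0.584). In the epithelial list 7 of 17 fell and 3 rose, and in the mesenchymal list 6 of 19 fell and 4 rose (camera adjusted p 0.381). The fetal liver list had 6 falls and 2 rises among 16 genes (camera adjusted p 0.117). Camera called none of these 7 lists, whereas fry called all but fatty acid oxidation (0.537) lower, with adjusted p-values from 4.14e-04 to 0.0125.

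Of 1056 genes with microRNA names, whose rows do not show whether the precursor or the mature form was read, 113 rose and 44 fell. They belong to the small RNA names that leaned upward. MIR222, under background level on 1 DMSO array, rose to 13.06, and MIR221 rose by 3.53. MIR21 rose by 3.67. MIR29B1 was at background level under DMSO and rose at least 18.2-fold. The adjusted p-values in limma of these 4 genes were 3.50e-05, 3.96e-04, 1.13e-04 and 2.95e-04.

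The rise of proteasome subunits did not extend to every proteasome gene. As a hypothesis, subunits and assembly factors outside the fixed list may rise too, but of 11 such genes 5 rose and 6 fell (camera p 0.367), with ADRM1 at 1.09 and PSMD5 at -1.49. As a further hypothesis, the immunoproteasome genes may rise with the constitutive ones, but 0 of 5 rose and 4 fell by limma, including PSME2 (-1.10), a subunit of the activator. The differences of all 5 were negative, so a looser threshold could not add a rise. PSMB8, PSMB9 and PSMB10 averaged 5.14, 5.10 and 4.79 under DMSO, near the background levels of 4.54 and 5.10 on those arrays.

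TGFB2 was among the largest falls. As a hypothesis, other targets of the YAP and TEAD transcription factors may fall too, but of 20 such genes not looked at before 8 fell and 5 rose (camera p 0.265). Targets already seen, among them TGFB2 and THBS1, which fell, and CCN1, which rose, were left out, so these counts are not those of all targets. ANKRD1, at background under DMSO, rose at least 7.03-fold.

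Splitting the 4 arrays into 2 and 2 in other ways gave at most 0 called genes in limma, against 8091 for the real split, which was 1 of 3 splits. At an unadjusted p under 0.05 the other splits gave 113 and 89 genes and the real one 10002. Each other split puts 1 zerumbone and 1 DMSO array in each group, so the difference between the treatments enters its residual spread. Its low counts therefore do not show how many calls would arise without a treatment effect. A share under 0.05 cannot be reached with 3 splits.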
